A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

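Poly(A) RNA was sequenced from 18 samples of asynchronously growing Saccharomyces cerevisiae, 6 for each of 3 strains (WT, K467N and K467R). By the labels, cells grew at 25 °C in rich medium with 2% glucose and adenine, from an optical density of 0.1 to between 0.6 and 0.7, and stranded libraries were made from 600 ng of RNA with 12 cycles of PCR. The deposited values are counts, raw and not normalised, with 1 count per gene and library. The processing notes name bcl2fastq 2.20.0.422, STAR 2.5.3a and HTSeq 0.6.1p1. The genome build, the annotation release and the strand setting are not given in the sources used here, so no coordinates are printed. Gene names, list membership, coding lengths and the order of genes along chromosomes were taken from the R64 annotation, to which 6078 of the 7036 features matched by identifier and 958 did not.

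Between 12395725 and 19093010 reads per library fell on genes, which was 75.3 to 76.2% of the reads HTSeq sorted. Reads with several alignments made up 18.3 to 19.6%, reads outside genes 4.70 to 5.64% and ambiguous reads 0.305 to 0.349%. The 10 highest genes took 12.7 to 14.5% of gene counts. TMM factors ranged from 0.910 to 1.06. None of the 153 pairs of libraries was a duplicate, with a chi-square per degree of freedom of 2.52 to 90.5 over genes with a summed count of at least 20. The reads carry no molecular identifiers, so intervals from counts cover counting error only.

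Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 5660 tested and 1376 not tested, and libraries were scaled by TMM. All 18 libraries entered 1 quasi-likelihood fit with robust dispersions and strain as the only term, and each of 3 contrasts was tested two-sided with Benjamini-Hochberg adjustment at 0.05. The labels give no batch, date or pairing. Principal components were computed on log2 CPM with a prior count of 2.

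Before the data were examined, 41 gene lists, the main tests, the comparisons and most alternatives were fixed. Lists with at least 3 tested members, 38 in all, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 38 lists of a comparison, and again with the correlation estimated for each list and with fry. The 16 nuclear chromosomes were tested as lists in the same way. The symbols MEL1, FLO8 and CRS5 matched no feature. A paralog was called near-identical at 95% identity or more over at least 50% of the coding length (BLAST 2.17.0), which marked 263 features.

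Genes were named by a rule fixed in advance. It takes NUP60, all genes that pass where fewer than 10 do, the 5 of smallest p among the rest, and up to 4 members of smallest p of each list called by camera and of 7 lists fixed for the question, and the text prints examples of these. Where 10 or more pass, it takes the 12 highest and 12 lowest with a mean of at least 5 CPM. Other genes are named only where a count of 5 or fewer or a neighbour called for it.

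Alternatives were DESeq2 size factors, upper-quartile scaling, no filter on low counts, a filter of 10 CPM in 6 libraries, DESeq2 1.42.0, limma-voom, limma-trend with array weights, a fit of the 12 libraries compared, 2 surrogate variables (sva 3.50.0), a test for changes over 1.2-fold, a threshold of 0.01, and leaving out each library in turn. A fit with a trend in coding length removed from each library and a fit without K467R 1 and K467N 2 were chosen after seeing the data. Shared changes of the 2 mutants were set against 100 simulations of unchanged strains with the same WT libraries in both contrasts, and against 20 assignments of WT libraries into 3 and 3. Counts of genes and lists were set against 100 of the 462 distinct splits of the 12 libraries compared.

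The steps were tested on simulated data with 200 changed genes per comparison. At 1.25-fold 58 to 78% of changed genes were recovered, at 1.5-fold 90 to 96%, and at 2-fold 98 to 100%. Between 2.65 and 4.86% of calls were unchanged genes. A list raised by 0.2 on the log2 scale was called in each comparison with both correlations, and 0 other lists were. Genes were simulated without correlation between them, so this does not test false calls of lists whose genes move together. Nor does it test false calls of genes where the genes of a library share variation. The highest counts of genes called in other splits of the real libraries were 1496, 1379 and 1 in the 3 comparisons. Among other splits of the real libraries, the median count of lists called was 8 for K467N against WT, 6 for K467R against WT and 6 between the mutants. Figures and the table of libraries that stand apart used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.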

Results

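The data were 18 poly(A) RNA libraries of budding yeast in 3 strains, with 6 libraries per strain. All strains carried NUP60 fused to GFP in the S288C background. Nup60 is a protein of the nuclear basket, the side of the nuclear pore that faces the chromosomes. WT had the normal lysine at residue 467, K467N had asparagine there as a mimic of acetylated lysine, and K467R had arginine as a mimic of lysine that stays deacetylated. The series asks whether acetylation of this lysine has a general role in transcription. By the labels, WT and K467N carried the HIS3 gene of Saccharomyces kluyveri as the marker at NUP60, and K467R carried the HIS3MX6 cassette, so marker and substitution change together in every comparison with K467R. Nothing in the labels says that the 6 libraries of a strain came from separate cultures, so each p-value measures only the spread between these samples. In the values below, ± after a log2 fold change is its standard error in edgeR, and ± after a level in CPM (counts scaled to a common library size) is the SD of 6 libraries.

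Reads counted on genes numbered 12395725 to 19093010 per WT library, 14061184 to 17111951 per K467N library and 12910660 to 15492932 per K467R library. Of the 7036 features in the files, 5660 had enough counts to be tested. The median 95% interval of a fold change spanned 0.14 log2 units to either side. Correlations of log2 CPM between libraries had a median of 0.995 within strains and 0.994 between strains. The first principal component held 37.4% of the variance, and 31.0% of it lay between strains. It ran from K467R 1 at -19.7 and K467R 5 at -12.0 to K467N 2 at 15.5. The second component held 11.9%, and 71.6% of it lay between strains: K467R libraries lay between 1.09 and 9.17 and the other 12 between -7.01 and 1.24. HIS3, which had almost no reads in K467R (below), was among the genes, and genes were not scaled to equal variance. The components were not computed without HIS3, so how much of this separation rests on that 1 gene was not tested.

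**Figure D1:**
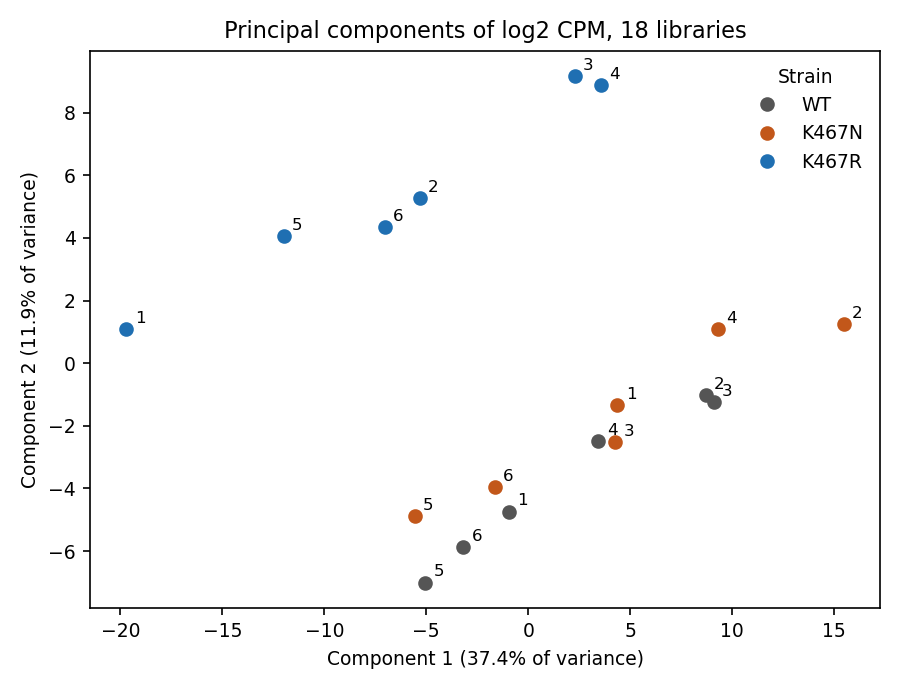
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library, coloured by strain and numbered by replicate. HIS3, almost without reads in K467R, is among the genes. On component 2, K467R libraries lie between 1.09 and 9.17 and WT libraries between -7.01 and -1.02, and on component 1 K467R 1 lies at -19.7 and K467N 2 at 15.5.

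The comparison of K467N with WT asks what the acetyl mimic changed. Of 5660 genes, 4 rose and 0 fell. AAD3 (YCR107W), a putative aryl-alcohol dehydrogenase gene, rose from 3.71 ± 0.274 to 12.1 ± 1.41 CPM (log2 fold change 1.71 ± 0.10, adjusted p = 2.66e-10). RDS1 (YCR106W), which encodes a zinc cluster transcription factor, rose from 5.27 ± 0.468 to 16.2 ± 3.47 CPM (1.61 ± 0.13, adjusted p = 1.41e-07). COS12 (YGL263W), a member of the subtelomeric COS family, rose from 1.69 ± 0.680 to 5.52 ± 1.12 CPM (1.69 ± 0.23, adjusted p = 0.00085). ADH7 (YCR105W), which encodes an alcohol dehydrogenase that uses NADPH, rose from 0.586 ± 0.129 to 1.77 ± 0.581 CPM (1.61 ± 0.24, adjusted p = 0.00226). Each of these genes was higher in all 6 K467N libraries than in any WT library.

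AAD3, RDS1 and ADH7 are the 3 outermost tested genes on the right arm of chromosome III, and COS12 is the outermost tested gene on the left arm of chromosome VII. Their inner neighbours were singled out after the values were seen. The next tested gene inward on chromosome III, YCR102C, had a log2 fold change of 0.08 ± 0.16, and the next on chromosome VII, VEL1, 0.23 ± 0.25. Over the outermost tested genes of the other 30 chromosome arms, 16 lay above 0, the median was 0.00389 ± 0.0391 and 0 passed the test. The highest of them was SEO1 at 0.38. In the whole list of subtelomeric genes, within 20 kb of a chromosome end, 4 of 122 tested members rose and 0 fell, with a median of -0.01, a mean of 0.05 and a positive camera test (adjusted p = 0.333). Adjusted over the list alone, 5 members rose, the fifth being YBL113C, which passed in only 6 of 18 fits that left out 1 library. AAD3 has a near-identical paralog, AAD15, and RDS1, ADH7 and COS12 have none.

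**Figure D2:**
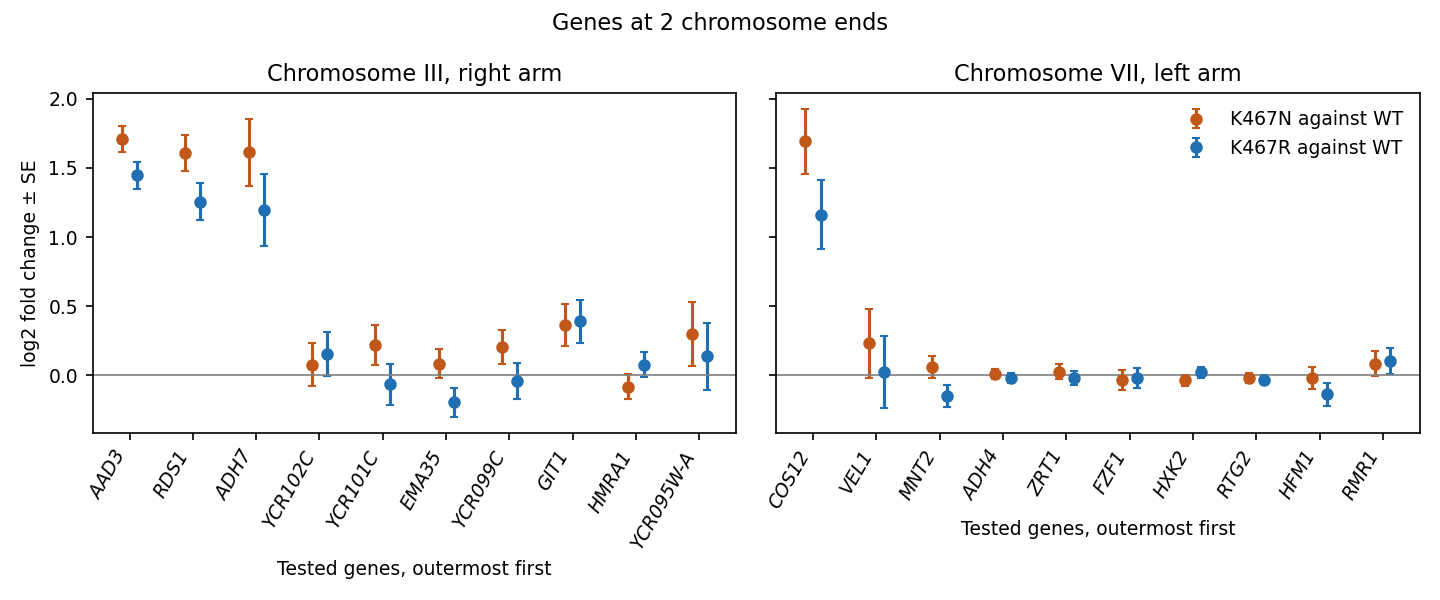
Log2 fold change against WT, with its standard error, of the 10 outermost tested genes on the right arm of chromosome III and the left arm of chromosome VII, for K467N and K467R. AAD3, RDS1, ADH7 and COS12 lie between 1.16 and 1.71, and the next genes inward, YCR102C and VEL1, lie between 0.02 and 0.23.

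The other tested genes differed little between K467N and WT. For 97.9% of them the log2 fold change lay within 0.25 of 0, and 65 had an unadjusted p under 0.05, of which 33 were lower, where 283 are expected by chance. That count was 141 with surrogate variables and 204 in limma-trend with array weights, 104 without WT 3, 39 without WT 5, 43 without K467N 4 and 117 without K467N 5, each still under the expected number. DESeq2 called 5 genes, with 1 lower (YFL065C, which had too few counts to be tested in edgeR), and limma-voom called 4 higher and 0 lower. The 5 genes with the smallest p-values that did not pass were YBL113C (0.29 ± 0.08), the F-box gene SAF1 (0.19 ± 0.06), AIP5 (0.16 ± 0.05), the aquaporin gene AQY2 (0.22 ± 0.07) and PIN2 (-0.19 ± 0.07), each with an adjusted p of 0.999. Libraries of the 2 strains did not overlap for 7 genes, where chance gives 12.3 (0.216% of genes).

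Of 38 gene lists, camera called 2 higher and 5 lower in K467N, and 0 of these 7 calls held with a correlation between genes estimated for each list. G1/S Start genes, the targets of SBF and MBF at the entry into S phase, had a median log2 fold change of 0.03 with 38 of 48 members above 0 (adjusted p = 0.000943, and adjusted p = 0.493 with an estimated correlation); examples are PRI2 at 0.06 and MCD1 at 0.06. The COS genes, 8 of which were tested, had a median of 0.04 and a mean of 0.22 (adjusted p = 0.0345, and adjusted p = 0.608 with an estimated correlation), with COS12 past the test and COS10 at 0.21 and COS8 at -0.24 not past it. Cytosolic ribosomal protein genes had a median of -0.05 with 5 of 137 above 0 (adjusted p = 2.74e-06, and adjusted p = 0.764 with an estimated correlation), but of 0.00417 without K467N 2, which turns its direction. Glycolysis genes had a median of -0.05 with 0 of 17 above 0 (adjusted p = 0.000269, and adjusted p = 0.608 with an estimated correlation), among them ENO1 at -0.18 and TDH1 at -0.21. Nuclear genes of the respiratory chain had a median of -0.05 (adjusted p = 0.00157, and adjusted p = 0.630 with an estimated correlation), with RIP1 at -0.10 and ATP2 at -0.06. Amino acid biosynthesis genes under Gcn4 had a median of -0.02 (adjusted p = 0.00637, and adjusted p = 0.608 with an estimated correlation), with LYS9 at -0.10 and LYS12 at -0.07. The 4 tested PAU genes, a seripauperin family, had a median of -0.26 (adjusted p = 0.00637, and adjusted p = 0.170 with an estimated correlation), with PAU23 at -0.27. Apart from COS12, no member of these 7 lists passed the test of single genes, adjusted over all genes or adjusted over the list alone.

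The calls of G1/S Start, glycolysis and PAU genes held in each of the 18 fits that left out 1 library. The COS genes were not called without WT 6, K467N 2 or K467N 4, the ribosomal protein genes without WT 1, K467N 2 or K467N 4, and the respiratory chain without WT 5, K467N 2 or K467N 4. Nor were the Gcn4 genes called without WT 6, K467N 3 or K467N 4. Over these fits the medians ran from 0.00285 to 0.073 for COS genes, from -0.0824 to 0.00417 for ribosomal protein genes, from -0.0816 to -0.0303 for glycolysis, from -0.0804 to -0.0173 for the respiratory chain and from -0.0262 to -0.00457 for Gcn4 genes. With surrogate variables the median of the COS genes was -0.0118. Leaving out a library raised the count of lists from 7 to 13 without WT 2, 16 without WT 3, 11 without WT 4, 11 without K467N 1, 12 without K467N 5 and 12 without K467N 6, and lowered it to 5 without K467N 4. Of the 7 lists, 3 were called without K467N 4 and 4 without K467N 2. The median of the ribosomal protein genes was 0.00132 in place of -0.0459 without K467R 1 and K467N 2, the libraries at the ends of the first component, and -0.0127 with a trend in coding length removed from each library.

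**Figure D3:**
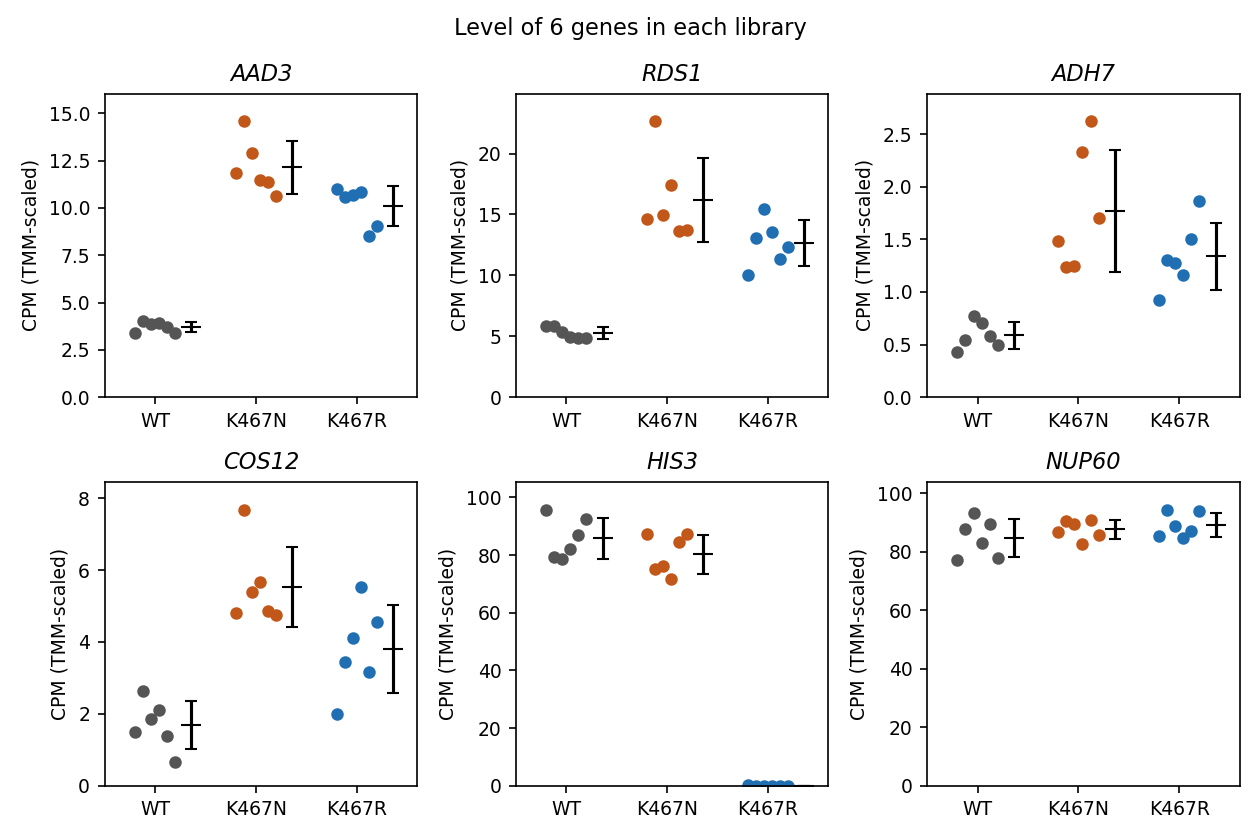
Level in TMM-scaled CPM of AAD3, RDS1, ADH7, COS12, HIS3 and NUP60, with 1 point per library in each strain and, beside them, the mean and SD of 6 libraries. AAD3 had means of 3.71 in WT, 12.1 in K467N and 10.1 in K467R, and HIS3 had 85.8, 80.3 and 0.0118.

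The comparison of K467R with WT asks what the mimic of deacetylated lysine changed. Here 2 of 5660 genes rose and 2 fell. AAD3 rose to 10.1 ± 1.06 CPM (log2 fold change 1.45 ± 0.10, adjusted p = 5.06e-09) and RDS1 to 12.6 ± 1.88 CPM (1.26 ± 0.13, adjusted p = 1.19e-05), again with all 6 libraries above every WT library. ADH7, at 1.34 ± 0.320 CPM (1.19 ± 0.26, adjusted p = 0.158), and COS12, at 3.80 ± 1.22 CPM (1.16 ± 0.25, adjusted p = 0.151), did not pass, although 6 and 5 of their K467R libraries lay above every WT library. The next genes inward, singled out as before, were YCR102C at 0.16 ± 0.16 and VEL1 at 0.02 ± 0.26. Over the outermost genes of the other 30 arms the median was -0.0696 ± 0.0464, with 7 above 0, 0 past the test and a highest value of 0.41 in THI13. Of the 122 subtelomeric genes 2 rose and 0 fell, with a median of -0.04. Adjusted over the list alone, 4 rose (AAD3, RDS1, ADH7 and COS12) and 2 fell (COS1 and the arsenite exporter gene ARR3, which passed in 11 of 18 fits that left out 1 library).

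HIS3 (YOR202W), which encodes an enzyme of histidine biosynthesis, fell in K467R from 85.8 ± 7.12 to 0.0118 ± 0.0290 CPM (adjusted p = 1.53e-21). The 6 WT libraries held 7468 HIS3 counts, the 6 K467N libraries 7394 and the 6 K467R libraries 1, with 0 counts in 5 of them. The ratio of WT to K467R was 7302, with a 95% interval of 1310 to 288457 for counting error alone. The genes on either side, chosen after this value was seen, had log2 fold changes of -0.03 ± 0.05 (MRM1) and -0.06 ± 0.05 (DED1). PHM8 (YER037W), a phosphatase gene of the phosphate regulon, fell by 0.34 ± 0.06 on the log2 scale, from 15.1 ± 0.892 to 11.9 ± 0.536 CPM (adjusted p = 0.0427), and was lower in all 6 K467R libraries than in any WT library.

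Calls at the edge of the threshold changed with the libraries and the tool. PHM8 did not pass in 16 of the 18 fits that left out a library, all except those without WT 1 or K467N 6, and its adjusted p ranged from 0.016 to 0.180 over 29 alternatives. COS12 passed in 5 of 28 alternatives: with surrogate variables (1.38, adjusted p = 2.86e-05), in DESeq2 (adjusted p = 0.00194), in limma-trend with array weights (adjusted p = 0.00437), without K467R 1 (1.29, adjusted p = 0.0187) and without K467R 1 and K467N 2 (adjusted p = 0.00572). Its adjusted p was at most 0.484. Besides COS12, DESeq2 called GCN4 lower (-0.12, adjusted p = 0.0046), and limma-trend with array weights called ADH7, COS12 and GAS4 higher and COS1 lower, genes with an adjusted p of 0.158, 0.151, 0.341 and 0.229 in edgeR.

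Across all genes, 96.6% lay within 0.25 of 0 on the log2 scale, and 321 had an unadjusted p under 0.05 where 283 are expected. That count lay on both sides of the expected number when a library was left out, at 196 without WT 2, 186 without WT 3, 189 without K467R 1 and 551 without K467R 4. Besides ADH7 and COS12, the genes of smallest p that did not pass were COS1 (-0.57 ± 0.13, adjusted p = 0.229), AIM33 (-0.45 ± 0.11, adjusted p = 0.341) and HEM3, which encodes porphobilinogen deaminase of heme synthesis (-0.16 ± 0.04, adjusted p = 0.341). GAS4 also had an adjusted p of 0.341 in edgeR. Libraries did not overlap for 16 genes, where chance gives 12.3.

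Of 38 lists, camera called 7 higher and 4 lower in K467R than in WT. With an estimated correlation 0 of these 11 calls held, with an adjusted p of 0.216 for the marker loci and 0.710 for each of the other 10. Cytosolic ribosomal protein genes had a median log2 fold change of 0.10 with 136 of 137 above 0 (adjusted p = 4.05e-17, and adjusted p = 0.710 with an estimated correlation), among them RPS9A at 0.18, RPL39 at 0.23 and RPL34A at 0.20. Ribosome biogenesis genes had a median of 0.02 (adjusted p = 0.0174, and adjusted p = 0.710 with an estimated correlation), with EBP2 at 0.13 and GAR1 at 0.14, and proteasome genes had a median of 0.06 (adjusted p = 0.0174, and adjusted p = 0.710 with an estimated correlation), with RPT4 at 0.11 and RPN11 at 0.08. Core histone genes had a median of 0.07 (adjusted p = 0.0276, and adjusted p = 0.710 with an estimated correlation), with HTB2 at 0.10 and HHF1 at 0.14. Heat shock and chaperone genes under Hsf1 had a median of 0.05 with SIS1 at 0.11, and methionine and sulfur assimilation genes a median of 0.03 with SAM2 at 0.10, both with an adjusted p of 0.0276, and of 0.710 with an estimated correlation. Amino acid biosynthesis genes under Gcn4 had a median of 0.04 but a mean of -0.18, which includes HIS3, and their test was positive (adjusted p = 0.0276, and adjusted p = 0.710 with an estimated correlation), with ILV5 at 0.20 and LEU1 at 0.12.

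The 4 lower lists, with an adjusted p of 0.216 for the marker loci and 0.710 for the other 3 with an estimated correlation, were the COS genes (median -0.15, mean -0.07, adjusted p = 0.0276), the iron regulon (median -0.13, adjusted p = 0.0276, FRE3 at -0.27 and FRE5 at -0.76), the auxotrophy and strain marker loci (median -0.06, adjusted p = 0.0222) and the meiosis and sporulation genes (median -0.09, adjusted p = 0.0493, IME2 at -0.34 and HOP1 at -0.24). The mean of the marker loci was -0.99, which includes HIS3 at -12.04, and 12 of their 13 tested members did not pass over all genes. Adjusted over the list alone, COS12 rose and COS1 and COS8 fell among the COS genes, HIS3 fell and MET17 rose (0.14) among the marker loci, HIS3 fell among the Gcn4 genes and PHM8 fell in the phosphate regulon. CPT1 (-0.21) and OPI1 (0.29) passed in the same way among the inositol and phospholipid genes, a list that camera did not call (median 0.01, adjusted p = 0.711). Of 18 fits that left out 1 library, MET17 passed in 14, CPT1 in 10 and OPI1 in 8, and without K467R 1 CPT1 was at -0.17 and OPI1 at 0.18, neither past the test (adjusted p = 0.102 over the list alone for both). Within the marker list LEU2 had a log2 fold change of -0.16.

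Of the 11 calls, that of the ribosomal protein genes held in each of the 18 fits that left out 1 library, with medians from 0.0596 to 0.127. The marker loci were not called without K467R 6, the ribosome biogenesis genes without WT 5, WT 6 or K467R 3, the proteasome genes without WT 2, WT 3 or K467R 5, and the methionine genes without WT 4, K467R 3 or K467R 5. Nor were the COS genes called without WT 1, WT 3, K467R 1 or K467R 5, the Gcn4 genes without WT 2, WT 4, K467R 1, K467R 3 or K467R 5, and the iron regulon without WT 2, WT 3, WT 4, K467R 2 or K467R 6. The Hsf1 genes were not called without WT 1, WT 2, WT 3, WT 4, K467R 1 or K467R 5. The core histone genes were not called without WT 2, WT 3, K467R 1, K467R 2, K467R 4, K467R 5 or K467R 6. The meiosis genes were called in 6 of the 18 fits, those without WT 2, K467N 1, K467N 2, K467N 3, K467N 4 or K467R 2. Medians ran from 0.000884 to 0.0294 for ribosome biogenesis, from 0.029 to 0.0733 for the proteasome, from 0.0384 to 0.102 for core histones and from 0.0261 to 0.0582 for Hsf1 genes. They ran from 0.0299 to 0.0564 for methionine genes, from 0.022 to 0.0529 for Gcn4 genes, from -0.192 to -0.0557 for the iron regulon, from -0.0962 to -0.0177 for the marker loci and from -0.135 to -0.0184 for meiosis genes. With surrogate variables the medians were -0.000128 for ribosomal protein genes, -0.00362 for the proteasome, -0.014 for core histones and 0.00124 for the marker loci, each of the other sign. The median of the core histones was -0.00161 with a trend in coding length removed. The count of lists fell from 11 to 7 without WT 2, 5 without WT 3, 6 without WT 4, 6 without K467R 1, 7 without K467R 3, 4 without K467R 5 and 7 without K467R 6. The median of the ribosomal protein genes was 0.0596 in place of 0.0973 without K467R 1 and K467N 2, and 0.0425 with a trend in coding length removed from each library.

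The direct comparison of the 2 mutants asks whether the opposite mimics differ. Only HIS3 passed in edgeR, higher in K467N (80.3 ± 6.76 CPM, adjusted p = 2.06e-21), and 0 genes were lower. DESeq2, limma-voom and limma-trend with array weights called the same gene alone. The ratio of K467N to K467R counts was 6767, with a 95% interval of 1214 to 267306 for counting error. The genes of smallest p that did not pass were COS1 (0.64 ± 0.13, adjusted p = 0.187, higher in all 6 K467N libraries than in any K467R library), and, each with an adjusted p of 0.408, PHM8 (0.26 ± 0.06), HEM3 (0.16 ± 0.04), YJL077W-A (-0.40 ± 0.10) and TVP38 (0.23 ± 0.06). COS12 differed by 0.53 ± 0.21 and ADH7 by 0.42 ± 0.21 (adjusted p = 0.408 for both). An unadjusted p under 0.05 was found for 635 genes, 331 of them lower, where 283 are expected, but for 216 with surrogate variables and 116 without K467R 1 and K467N 2, which are fewer than expected. Leaving out 1 library gave 233 without K467N 2, 273 without K467R 1, 320 without K467N 4, 334 without K467R 5, 1110 without K467R 3, 1202 without K467R 4 and 1215 without K467N 5. Libraries did not overlap for 16 genes, where chance gives 12.3, and 94.9% of genes lay within 0.25 of 0.

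Between the mutants, camera called 1 of 38 lists higher and 7 lower in K467N, and with an estimated correlation 0 of these 8 calls held. The COS genes were higher, with a median of 0.26 and all 8 above 0 (adjusted p = 0.000471, and adjusted p = 0.541 with an estimated correlation). Adjusted over the list alone, COS1, COS10, COS12 and COS111 passed, of which COS1 did so in 18 of 18 fits that left out 1 library, COS10 and COS12 in 12 and COS111 in 11. Cytosolic ribosomal protein genes were lower, with a median of -0.14 and 1 of 137 above 0 (adjusted p = 2.36e-24, and adjusted p = 0.750 with an estimated correlation), among them RPS9A at -0.20 and RPL39 at -0.27. Their median was -0.0547 in place of -0.141 without K467R 1 and K467N 2, the libraries at the ends of the first component and also the highest K467R and lowest K467N library for this list, -0.0467 with a trend in coding length removed and -0.0129 with surrogate variables. Core histone genes had a median of -0.12 with HHF1 at -0.20, glycolysis genes -0.09 with TDH1 at -0.29, and proteasome genes -0.08 with PRE7 at -0.13 and RPT4 at -0.10, each with an adjusted p of 0.00339, and of 0.750 with an estimated correlation. Gcn4 genes had a median of -0.07 but a mean of 0.15, which includes HIS3 (adjusted p = 0.000471, and adjusted p = 0.750 with an estimated correlation), with ARG1 at -0.16 and ILV5 at -0.20. Hsf1 genes had a median of -0.07 (adjusted p = 0.0244, and adjusted p = 0.750 with an estimated correlation) and respiratory chain genes -0.04 (adjusted p = 0.0263, and adjusted p = 0.785 with an estimated correlation). The other members that passed when adjusted over the list alone were HIS3 and MET17 among the marker loci, HIS3 among the Gcn4 genes, PHM8 in the phosphate regulon, CPT1 among the inositol and phospholipid genes, COS1 among the subtelomeric genes and SAG1 (0.25), 1 of 2 tested alpha-specific genes. Of 18 fits that left out 1 library, MET17 passed in 17, PHM8 in 16, CPT1 in 11 and SAG1 in 6.

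The Hsf1 genes were not called without K467N 1, K467N 2 or K467R 5, and the respiratory chain without K467N 2, K467N 4, K467R 1, K467R 2 or K467R 5. The other 6 lists were called in each of the 18 fits. The medians ran from -0.119 to -0.0482 (without K467R 1) for glycolysis, from -0.0995 to -0.0466 (without K467N 2) for the proteasome and from -0.154 to -0.0758 (without K467N 2) for core histones. They ran from -0.0901 to -0.0419 (without K467R 1) for Hsf1 genes and from -0.075 to -0.024 (without K467N 4) for the respiratory chain. With surrogate variables they were 0.0203 for the respiratory chain, 0.000132 for Hsf1 genes, 0.00307 for glycolysis and 0.0000505 for the proteasome, each of the other sign. The respiratory chain had 0.00391 with a trend in coding length removed. By fry, which tests whether a list's genes move one way on balance, the COS genes (adjusted p = 0.0403) and the subtelomeric genes (median 0.03, adjusted p = 0.0403) passed, together with the marker loci that hold HIS3. An exact two-sided permutation test on the mean log2 CPM of the ribosomal protein genes per library, over 924 assignments of 6 against 6, gave p = 0.0974 for K467N against K467R (adjusted 0.292), 0.210 for K467R against WT (adjusted 0.315) and 0.610 for K467N against WT (adjusted 0.610). The library differences behind these tests were -0.15, 0.10 and -0.04. Gene weights on the first principal component had a Spearman's rho of 0.58 with coding length, across 5527 genes, which are not independent replicates. The median coding length was 432 bases for ribosomal protein genes and 1236 for all genes.

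The direction of the median of each list called above, in the comparison that called it, was the same with DESeq2 size factors and with upper-quartile scaling as with TMM. Neither scaling moved the median of all genes by 0.1 or more.

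Of the genes that rose, 2 (AAD3 and RDS1) were shared by the 4 of K467N and the 2 of K467R. Independent lists would share 0.00141, and 100 simulations of unchanged strains gave a mean of 0.01 and at most 1. Neither value tests the overlap. The lists are not independent, since both use the same WT libraries, and strains simulated without changed genes have an overlap near 0 set in advance. Of the genes that fell, 0 were shared. Both contrasts use the same WT libraries, which alone makes their fold changes correlate. Across 5660 genes, which are not independent replicates, Pearson's r was 0.17 and Spearman's rho was -0.10. The simulations gave 0.502 ± 0.0188 and 0.470 ± 0.0116 (SD). They drew each gene independently, without the variation that genes of a library share. Their SD may therefore be too narrow, and they cannot show that the mutants share less than chance gives. The covariance was 0.00254 against 0.00489 in the simulations, a difference of -0.00235. With the WT libraries split into 3 for each mutant, r averaged -0.0616 over 20 assignments, from -0.413 to 0.152. The value of r moved to 0.253 without WT 5, 0.326 without K467N 2, 0.265 without K467R 1, 0.0309 without K467N 5, 0.0885 without K467N 6, 0.104 without K467R 3 and 0.0901 without K467R 4.

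NUP60 itself (YAR002W) was read at 84.6 ± 6.50 CPM in WT, 87.6 ± 3.19 in K467N and 89.1 ± 4.20 in K467R. Its log2 fold change was 0.05 ± 0.05 in K467N and 0.07 ± 0.05 in K467R against WT, and -0.02 ± 0.05 between the mutants (adjusted p = 0.999, 0.747 and 0.789). Of the 33 genes of the nuclear pore complex, 0 passed in any comparison by edgeR, DESeq2, limma-voom or limma-trend with array weights, and 0, 1 and 2 had an unadjusted p under 0.05 in K467N against WT, K467R against WT and K467N against K467R. Their medians were 0.04, -0.00268 (0.00358 with DESeq2 size factors) and 0.04, with camera adjusted p of 0.066, 0.762 (in a test that was positive) and 0.484. Examples are NUP85 at 0.09 and ASM4 at 0.08 in K467N and DYN2 at 0.21 in K467R. Of the 22 genes of mRNA export, 0 passed by any of the 4 tools, with 0, 1 and 1 at an unadjusted p under 0.05, medians of 0.01, 0.01 and -0.01 and adjusted p of 0.664, 0.548 and 0.731. Examples are MEX67 at 0.08 and DBP5 at 0.05 in K467N and THP2 at 0.17 in K467R. Adjusted over the list alone, 0 genes of either list passed.

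Genes of the cell cycle and of galactose use were fixed as lists because they bear on the entry into S phase and on genes that move to the nuclear pore. The cells grew asynchronously in 2% glucose, so the values do not cover growth in galactose or the timing of entry into S phase. In the 3 comparisons, in the order used above, the 48 G1/S Start genes had medians of 0.03, 0.01 and 0.03 and adjusted p of 0.000943, 0.406 and 0.450, and in K467N the adjusted p was 0.493 with an estimated correlation. The 15 Start regulators had medians of 0.02, 0.02 and 0.01 (adjusted p = 0.225, 0.803 and 0.648), with CLN3, the cyclin gene that starts the cycle, at 0.07, -0.12 and 0.18 and its opponent WHI5 at 0.19 and 0.20 in the 2 mutants, the value of K467R being 0.11 without K467R 1. The 10 tested genes of the galactose regulon had medians of -0.06, -0.07 and 0.01 (adjusted p = 0.291, 0.183 and 0.538), with GAL1 at -0.10 and -0.11 and GAL4 at 0.23 in K467N and 0.36 between the mutants. No member of these 3 lists passed in any comparison by the 4 tools, adjusted over all genes, nor in edgeR when adjusted over the list alone; at an unadjusted p under 0.05 the counts were 0, 5 and 5 for G1/S Start genes, 0, 1 and 1 for Start regulators and 0, 0 and 1 for the galactose regulon. The marker loci had adjusted p of 0.318 in K467N against WT and 0.111 between the mutants, with medians of -0.01 and 0.07.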

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

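The tests on the 4 genes at chromosome ends and on HIS3, the difference predicted from depth, the fit without K467R 1 and K467N 2 and the fits with a trend in coding length removed were chosen only after the results were seen.

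AAD3, RDS1, ADH7 and COS12 were higher in both mutants than in WT, at 2 chromosome ends, with COS12 and ADH7 past the test in K467N and not in K467R, and with no difference between the mutants past it (0.53 ± 0.21 and 0.42 ± 0.21, adjusted p = 0.408). A release of repression at every chromosome end would raise the outermost genes elsewhere. The higher of the 2 medians over the outermost tested genes of the other 30 arms was 0.00389. These ranged in WT from low levels, such as VTH1 at 0.759 CPM, to high ones, such as CHA1 at 304 CPM. Genes with too few counts to be tested were left out. The medians show no general rise of the tested genes, but cannot exclude a release at silent ones. Of the 4 genes, 3 have no near-identical paralog that could lend reads. With 1 extra copy of the right end of chromosome III in every cell, the log2 fold change would be 1. This holds if WT has 1 copy and levels follow the number of copies. The lower of the 2 weighted means of AAD3, RDS1 and ADH7 was 1.37 ± 0.0753, in K467R, or 4.85 standard errors above 1. From 2 extra copies (1.58), K467N lies 1.17 standard errors away, at 1.67 ± 0.0733, and K467R -2.92. The 3 genes were picked for their rise, and their standard errors were combined as if independent. These distances may therefore be too large, and extra copies are not excluded. A low level particular to the WT strain, and no effect of either substitution, was not tested, since the 4 of 4 genes above 0 in both mutants are the pattern itself, and with 1 WT strain it cannot be told apart from an effect that both substitutions share. An effect of the substitutions on these 2 chromosome ends is the biological explanation that the design offers, and it was not tested further.

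HIS3 differed between the K467N and K467R strains, which also differ in their marker, with a ratio of K467N to K467R of 6767. In K467R the value of K467R 1, with the single HIS3 count, stands apart from the other 5 at 0 (gap over range 1). A single count beside 5 libraries at 0 always gives this gap. A wider loss around the locus would lower its neighbours, but the larger change of MRM1 and DED1 was -0.0622, and single mislabelled libraries would leave some K467R libraries with HIS3, but 6 of 6 lie below all 12 others. A HIS3 allele without transcribed HIS3 sequence in the K467R strain could account for the loss. The highest K467R library reached 0.0827% of the WT mean, and the labels name another marker cassette there. Whether the HIS3 reads of WT and K467N came from HIS3 itself or from their S. kluyveri HIS3 marker was not tested. Marker and substitution change together in K467R, as would a different HIS3 allele if present, so the other differences of K467R were not separated from them.

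Ribosomal protein genes were higher in K467R than in K467N by camera, with a median difference of -0.141 for K467N against K467R (adjusted p = 2.36e-24, and adjusted p = 0.750 with an estimated correlation), and of -0.0129 with surrogate variables. Sequencing depth does not account for this: K467N libraries were the deeper (mean gene counts of 15135899 against 14422656), and by the slope within strains these depths predict a difference of 0.0148, with a 95% interval of -0.0187 to 0.0484, against -0.148 in the library means. Spearman's rho of the list's mean and the total gene count was 0.257 over 18 libraries (permutation p = 0.304, Pearson's r 0.151 with permutation p = 0.551, 0.240 without the 2 libraries farthest in depth), and within WT, K467N and K467R it was 0.771, 0.0286 and 0.314. A bias by coding length that differs between libraries may account for most of the difference, since the median was -0.0467 once a trend in coding length was removed from each library, and -0.0539 with the trend fitted without the ribosomal protein genes. Removing the trend would also take away a real change shared by short genes, so these values cannot tell a bias from such a change. The 2 libraries at the ends of the first principal component stay open: the median was -0.0547 without K467R 1 and K467N 2, but these are the highest K467R and the lowest K467N library for this list (10.6 and 9.98 mean log2 CPM), which fixes a fall, and a difference between the substitutions stays open as the biological explanation, at a size that an exact permutation test over libraries did not pass (p = 0.0974, and 0.203 with the trend removed).

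The counts of genes were set against other splits of the same 12 libraries, 100 per comparison with the real one included. For K467N against WT, 4 splits called as many as the real 4 genes, and for K467R against WT 2 splits called as many as the real 4. For K467N against K467R, 2 called as many as the real 1. Few splits thus reached the real counts of genes, though others than the real one did. By a rule fixed before the data were examined, a share of splits under 0.05 speaks against chance. Each comparison stayed under it, which argues against chance for the counts of genes without excluding it. The highest other splits called 1496, 1379 and 1 genes. Splits that called over 100 genes, 3 for K467N against WT and 1 for K467R against WT, point to a structure of the samples: they had the largest differences along the first principal component, at least 8.42 and 13.1, against 2.36 and 8.37 in the real splits. For gene lists, 60 splits called as many as the real 7 (highest other 16), 11 as many as the real 11 (highest other 12) and 32 as many as the real 8 (highest other 12), so chance is not excluded for the counts of lists.

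YFL065C, a gene at the left end of chromosome VI with too few counts to be tested, had a log2 fold change of -2.70 ± 0.44 in K467N when no filter was used (adjusted p = 0.00425), from 53, 8 and 34 counts in WT, K467N and K467R, and it has near-identical copies at many other chromosome ends.

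In 19 of 267 groups of 6 libraries a library stood apart from the other 5, where chance gives 13.4 (about 1 in 20). K467R 1 stood apart in WHI5 (gap over range 0.644), CKS1 (0.740) and ELO1 (0.795), besides HIS3, where its single count fixes the gap. K467N 2 stood apart in COS12 (0.687, at 7.68 CPM against at most 5.67) and RPN11 (0.683), and WT 5 in YJL077W-A (0.719), RIP1 (0.642) and MET17 (0.632). WT 1 did so in its gene counts (0.737, 19093010 against at most 14159125) and in VEL1 (0.640). The others were AIM33 in K467R 6 (0.752), YCR102C in K467R 2 (0.642), VEL1 in K467R 4 (0.677), MEX67 in K467N 5 (0.657), MCD1 in K467N 6 (0.726), PAU23 in K467N 4 (0.684), HOP1 in WT 2 (0.837) and EBP2 in WT 4 (0.769).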

How the results depend on the processing

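The fit with a trend in coding length removed and the fit without K467R 1 and K467N 2 were chosen only after the results were seen; the other alternatives were fixed before. The medians of called lists, the counts at an unadjusted p under 0.05 and the passes adjusted over the list alone were computed for the alternatives only after the results were seen.

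AAD3, RDS1, COS12 and ADH7 in K467N, AAD3 and RDS1 in K467R, and HIS3 in K467R and between the mutants kept their direction and stayed past the threshold in each alternative that tested them. PHM8 in K467R did not pass in 23 of 29 alternatives. The count for K467N against WT was 4 or 5 except with a filter of 10 CPM in 6 libraries, which removes ADH7 and COS12 and left 2. For K467R against WT it was 3 to 6 except with limma-trend and array weights, which called 8 (5 higher, 3 lower), and the cause was not tested. Between the mutants it was 1 in each alternative. Without 1 library the counts were 4, 3 to 4 and 1. The log2 fold change of NUP60 passed in no alternative and kept its sign.

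The counts of lists, 7, 11 and 8, became 0, 0 and 0 with an estimated correlation and 0, 1 and 3 with fry. The preset correlation was 0.01. The estimate was 0.891 for ribosomal protein genes, 0.824 for core histones, 0.578 for glycolysis and 0.481 for the respiratory chain. For such lists the preset test takes genes that move together as nearly independent, so its p-values are too small. The estimate was 0.0595 for G1/S Start genes, -0.00589 for the marker loci and -0.0868 for PAU genes. Lists without members that have a near-identical paralog gave 7 for K467R against WT, with fewer genes per list. With the trend in coding length removed the counts were 5, 13 and 10, and without K467R 1 and K467N 2 they were 7, 9 and 7. Without 1 library they ranged from 5 to 16, from 4 to 11 and from 6 to 12. Apart from these correlations, the cause of the changes was not tested.

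The correlation of the fold changes of the 2 mutants, 0.167, was -0.0616 with 3 WT libraries for each mutant, which takes away the shared WT libraries, 0.0314 with the filter of 10 CPM and 0.114 without the called genes. Without 1 library it ranged from 0.0309 to 0.326. No gene that passed reversed its direction, but medians of called lists did. Ribosomal protein genes in K467N went from -0.0459 to 0.00417 without K467N 2 and 0.00132 without K467R 1 and K467N 2. With surrogate variables the COS genes in K467N had -0.0118, and in K467R ribosomal protein genes had -0.000128, core histones -0.014, the proteasome -0.00362 and the marker loci 0.00124. Between the mutants the respiratory chain had 0.0203, Hsf1 genes 0.000132, glycolysis 0.00307 and the proteasome 0.0000505. With the trend in coding length removed, core histones had -0.00161 in K467R and the respiratory chain 0.00391 between the mutants. The cause of these changes was not tested.

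No paired analysis was made because the labels number the libraries from 1 to 18 and name no replicate shared between strains. Whether libraries of the same replicate number in different strains belong together was not tested. Depth limits genes of few counts: ADH7 lay at 0.586 CPM in WT, and 1376 features were not tested.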

Other observations

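No test in this part was chosen after the results were seen, except that the untested genes at 2 chromosome ends were singled out by their counts.

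Other gene groups gave small values in K467N and K467R against WT and passed in neither by camera. Median log2 fold changes were 0.01 and -0.01 for acetyltransferases and deacetylases, 0.04 and -0.03 for the G2/M CLB2 cluster, 0.01 and -0.00355 (0.00291 with DESeq2 size factors) for M/G1 genes of Swi5 and the early cell cycle box, and -0.04 and -0.02 for the general stress response. They were 0.01 and -0.05 for hexose transporters, -0.03 and -0.05 for glucose-repressed carbon metabolism, 0.03 and -0.03 for zinc and copper genes, 0.01 and -0.02 for ergosterol biosynthesis, and -0.02 and -0.02 for purine and one-carbon genes. The cell wall integrity genes had -0.04 and -0.02, the phosphate regulon -0.01 and -0.03, and pheromone response genes 0.03 and -0.00532 (0.00103 with DESeq2 size factors). Genes with introns other than ribosomal protein genes had -0.01 and 0.02, and non-polyadenylated RNAs such as snoRNAs 0.03 and 0.03.

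In some lists that did not pass, the mean had another sign than the median. In K467N against WT these were the M/G1 genes (mean -0.00155, negative test), hexose transporters (-0.00918, positive test), meiosis genes (median 0.01, mean -0.01, positive test), the phosphate regulon (0.006, negative test) and the subtelomeric genes (median -0.00694, mean 0.0452, positive test). In K467R against WT they were glucose-repressed carbon metabolism (0.03, positive test), the general stress response (0.00557, negative test), purine and one-carbon genes (0.01, negative test) and non-polyadenylated RNAs (-0.02, positive test). In K467N against K467R they were the inositol and phospholipid genes (median -0.00137, or 0.000739 with upper-quartile scaling, mean 0.02, positive test).

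The 10 neighbours of NUP60 had medians of 0.0016 and 0.03. The a-specific genes, 7 of 7 tested, had 0.02 and 0.09, and the 2 tested alpha-specific genes had 0.01 and -0.02. No nuclear chromosome was called in any of the 3 comparisons, with medians between -0.0335 and 0.0302 over the 16 chromosomes. Of the 55 genes encoded in mitochondria 0 had enough counts to be tested, and 0 features of the count files matched the list of Ty elements, which were therefore not tested.

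At the chromosome ends with raised genes, some genes had too few counts to be tested. YGL262W, beside COS12, had 2 counts over the 6 WT libraries, 21 in K467N and 16 in K467R. PAU11, next to it, had 12, 22 and 13, and PAU3, inward of ADH7, had 24, 34 and 19.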
